A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

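Total RNA of Saccharomyces cerevisiae was sequenced from 18 samples, 3 in each of 6 groups. Per the labels' protocols, cells grew in rich medium (YPD) at 30 °C to exponential phase at an optical density of 0.6, ribosomal RNA was removed with Ribo-Zero, and stranded TruSeq libraries were made. The first series held a wild type and a upf1 deletion. The second held a wild type, an nmd4 deletion, an ebs1 deletion and a strain labelled nmd4 ebs1 double deletion. UPF1 is called NAM7 in the annotation. The labels give the labelled double deletion another parent strain (BY4742, mating type alpha) than its wild type (BY4741, mating type a), so background and genotype are confounded there.

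Each series came as its own table of read counts per feature, per the file headers made by the authors with featureCounts (Subread 1.5.0-p3). The submitters' processing notes and the headers give alignment with STAR 2.4.2a to the R64 genome, counting on the sense strand, reads assigned to every feature they overlap, and no reads with more than 1 alignment. Genes with near-identical copies therefore lose reads, and overlapping genes share them. The deposited counts carry no scaling. Both tables list the same 12289 features, among them 6008 coding features, 1658 Xrn1-sensitive unstable transcripts (XUTs), 925 cryptic unstable transcripts (CUTs), 1315 CUTs from a further annotation, 847 stable unannotated transcripts (SUTs), 705 open reading frames outside RefSeq, 281 introns and 550 other features. Of 6713 features with an open reading frame identifier, 6029 matched a RefSeq gene. Coding features include untranslated regions, and 682 overlap another gene on the same strand. 1 feature had a negative length of -100 bases, and feature lengths entered only intron densities and the matching of random sets.

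Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and tables and plots were made in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9). Features were kept by filterByExpr, scaled with TMM and tested with edgeR's quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The upf1 series was fitted on its 6 libraries (9700 features tested). The second series was fitted on its 12 libraries with 4 groups (10148 features tested), giving 3 mutants against wild type, the labelled double deletion against each single deletion, and the interaction. A fit of all 18 libraries (10381 features) tested the upf1 effect, taken within its own series, minus each other effect. Fold changes are log2 values of the edgeR fit at its default prior count, and a prior count of 2 applied to log2 CPM values. Standard errors are the absolute log2 fold over the square root of the F statistic. Abundances are CPM (counts scaled to a common library total after TMM). Where a group had 3 counts or fewer per library, CPM values are given and no fold, except for fitted interaction values. p-values measure only the spread between these samples, since the labels do not say that the samples of a group came from separate colonies.

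Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. 25 lists were fixed: NMD and decapping factors, known NMD substrates, mRNAs with upstream reading frames regarded as NMD-resistant, telomere maintenance, pyrimidine synthesis, arginine synthesis, Gcn4 target amino acid synthesis, sulfur and methionine, lysine synthesis, cytosolic ribosomal proteins, ribosome biogenesis, environmental stress, Hsf1 chaperones, the iron regulon, copper genes, oxidative phosphorylation, glycolysis and fermentation, exosome and nuclear RNA decay, a-specific genes, alpha-specific genes, haploid pheromone response, meiosis and sporulation, stationary phase, auxotrophy loci, and neighbours of the deleted genes. 3 more lists were written after the values were seen: the PHO regulon, allantoin and urea use, and genes near the chromosome ends (subtelomeric genes). Set tests needed at least 3 members. The upf1-raised set held features with a log2 change of at least 1 and an adjusted p under 0.05 in the upf1 deletion, and the upf1-lowered set its mirror. Intron counts were also set against the exon counts of the same genes as a density per base, with an exact permutation test across libraries whose smallest possible p is 0.1. An exact sign-flip test over same-numbered pairs was added after the values were seen.

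The genes named for a comparison were fixed by rule: the deleted genes; the 12 largest rises and 8 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out deleted, mating-type and auxotrophy genes; up to 4 members with the smallest p of each list described, with every known NMD substrate that passed; and up to 6 genes with the smallest p for an interaction or a difference. Chance separates 3 libraries from 3 in 10% of genes. This rule, the groups, tests, lists and the other settings listed here were chosen before the data were examined.

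The labels state that same-numbered samples were handled in parallel, so the numbers pair the samples. Across features, deviations from the group means of same-numbered libraries correlated at 0.04 to 0.23 in the upf1 series (median of 3 pairs 0.13, against -0.07 for 6 other pairs), and at -0.01 to 0.65 in the second series (median of 18 pairs 0.47, against -0.23 for 36 other pairs). The planned fits had no block. A fit with the replicate number as a block was an alternative, and its value stands beside a result only where it changed a call or moved a count by more than 1.5 times.

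Other alternatives were relative log expression (RLE) scaling, scaling on coding features alone, no filter on low counts, DESeq2 1.42.0 with and without the block, fits of only the libraries compared, fold minimums of 1.5 and 2, and leaving out each library. The correlation expected from shared control libraries was taken from 50 simulations of unchanged groups without replicate effects, and, added after the values were seen, from 50 with the replicate effects of the block fit. No library was a copy of another: chi-square per degree of freedom between libraries of a group was 13.6 to 77.5. The fits were tested on simulated data. In the simulated upf1 comparison (9572 features) 72.6%, 97.1% and 100% of features changed by a log2 of 0.5, 1 and 2 were called, with 8.59% of calls false. In the simulated ebs1 comparison (10079 features) the shares were 14.7%, 64.9% and 96%, with 6.3% of calls false. Changes were set on 62, 69 and 69 features for upf1 and 68, 57 and 75 for ebs1. They ran in both directions, on features with enough counts and without replicate effects. These shares may not hold for the real upf1 comparison, where 3592 features were called higher and 3086 lower of 9700. The biological coefficient of variation was 0.08 in the upf1 series and 0.18 in the second, which sets how small a change could be seen.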

Results

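RNA of budding yeast was counted over 12289 coding, non-coding and intron features in 18 libraries to ask how transcript levels change without factors of nonsense-mediated mRNA decay (NMD), the pathway that degrades mRNAs with early stop codons. UPF1 (NAM7) encodes the core NMD helicase, and NMD4 and EBS1 encode proteins found with it. In the upf1 series replicates 1, 2 and 3 of the wild type held 26880135, 21636349 and 26288427 counts in total, and those of the upf1 deletion 21729219, 25968945 and 22736414. In the second series the wild type held 18537270, 14243384 and 29742476 counts, the nmd4 deletion 19947688, 28147469 and 26898660, the ebs1 deletion 21615023, 26151830 and 23396952, and the labelled double deletion 20182074, 21174029 and 31452109. The first principal component held 85.5% of the variance in the upf1 series and separated the genotypes. In the second series the first component (25.8%) set the labelled double deletion apart, and the second (22.6%) followed the replicate number.

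The deleted genes were read first, as a check of the labels. NAM7 (YMR080C, chromosome XIII, 426310 to 429710) fell from 251 ± 5.18 CPM (SD, n = 3) in wild type to 8.78 ± 0.37 CPM in the upf1 deletion, which is 3.5% of wild type. EBS1 (YDR206W, chromosome IV, 861720 to 864864) fell from 142 ± 13.1 CPM to 3.67 ± 0.685 CPM in the ebs1 deletion and to 4.83 ± 1.05 CPM in the libraries labelled nmd4 ebs1 double deletion. NMD4 (YLR363C, chromosome XII, 851956 to 853228) fell from 27.2 ± 4.36 CPM to 2.87 ± 0.853 CPM in the nmd4 deletion. It was not lost in the libraries labelled nmd4 ebs1 double deletion: there it stood at 73.6 ± 8.62 CPM, 2.71 times wild type (log2 1.44 ± 0.18 SE, adjusted p = 0.000888, edgeR). Directions drawn from these libraries therefore belong to a label that NMD4 goes against. NMD4 also rose 4.24-fold and EBS1 2-fold in the upf1 deletion (adjusted p = 6.52e-10 and 1.38e-07, edgeR). In the ebs1 deletion NMD4 stood at 1.76 times wild type (log2 0.81 ± 0.18, adjusted p = 0.0765, edgeR), which passed with the replicate block (adjusted p = 0.02).

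**Figure D1:**
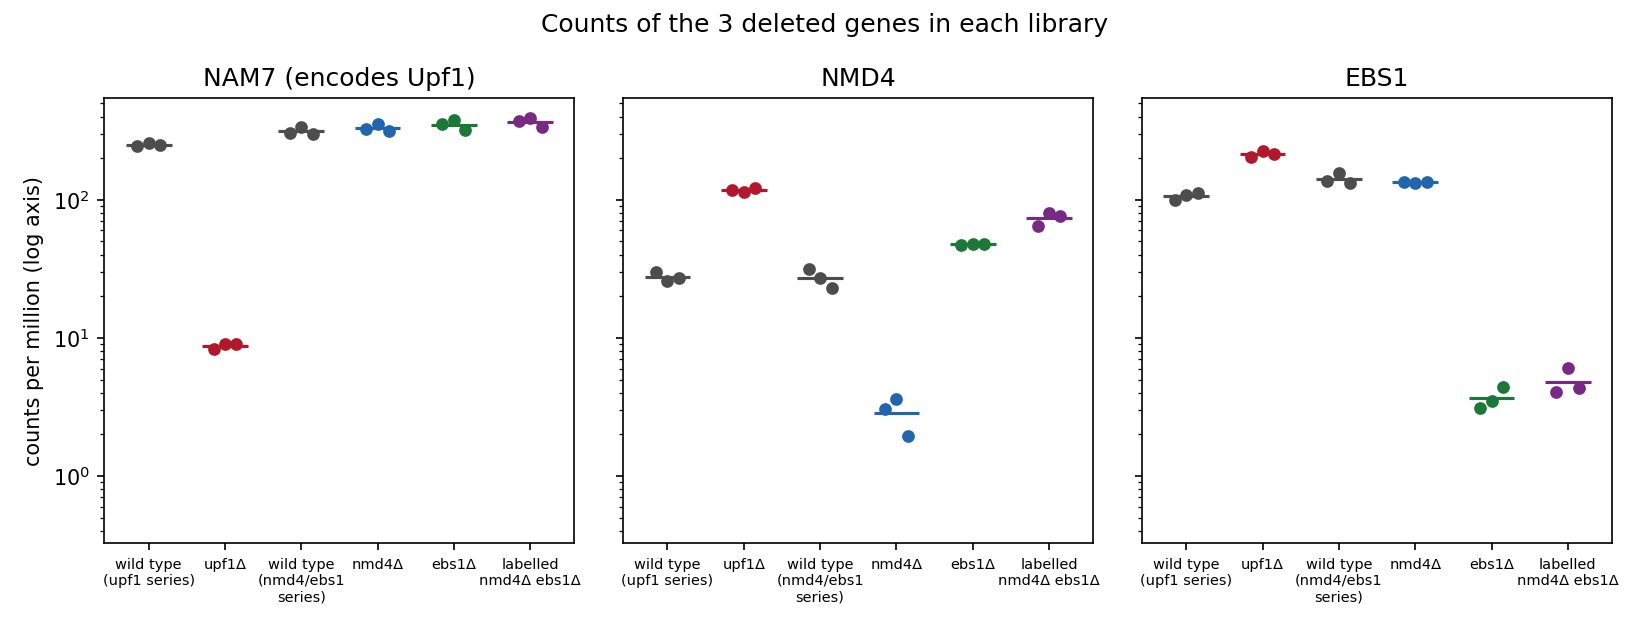
Abundance (CPM, log axis) of NAM7, NMD4 and EBS1 in each of 18 libraries by group; points are libraries and lines are group means. NMD4 averaged 2.87 CPM in the nmd4 deletion and 73.6 CPM in the libraries labelled nmd4 ebs1 double deletion.

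The markers of background matched the labels' strains. The labelled double deletion had 0.072 ± 0.0442 CPM of LYS2 (a lysine synthesis gene deleted in BY4742) against 343 ± 32.9 CPM in wild type, and 350 ± 94.4 CPM of MET17 (a sulfur gene deleted in BY4741), which had 0 to 3 counts per library in the other groups. The alpha-factor gene MF(ALPHA)1 stood at 941 ± 118 CPM and the a-factor receptor gene STE3 at 415 ± 39.5 CPM, while the alpha-factor receptor gene STE2 went from 450 to 6.17 CPM. The a-specific list had 7 genes lower (adjusted p = 1.23e-121, camera, or 5.45e-05 with an estimated correlation). The alpha-specific list had 4 of 5 higher (5 adjusted over the list alone, adjusted p = 1.23e-121, camera, or 1.3e-06 with an estimated correlation). Of 4 auxotrophy loci tested 1 was higher and 1 lower; their median was 0.16 while camera gave a fall (adjusted p = 0.00812, or 0.13 with an estimated correlation and 0.0588 with the replicate block).

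In the upf1 deletion the subtelomeric gene COS12 (YGL263W, chromosome VII, 2777 to 3969) went from 1.32 ± 0.21 to 35.2 ± 1.53 CPM (SD, n = 3; log2 4.74 ± 0.12 SE, adjusted p = 2.37e-10, edgeR). DAL7, which encodes a malate synthase of allantoin use, went from 22.8 ± 0.62 to 219 ± 6.77 CPM (log2 3.26 ± 0.06, adjusted p = 2.92e-11, edgeR), and the allantoate permease gene DAL5 rose 6.39-fold and the allantoicase gene DAL2 6.07-fold. STN1, whose product caps telomeres, went from 16.9 to 95.6 CPM (log2 2.50 ± 0.07). The other large rises were the sporulation genes ISC10 (2.90) and SPS4 (2.61), ULI1 (2.97), the peroxisomal import receptor gene PEX9 (2.67), the drug exporter gene FLR1 (2.65), the Golgi tethering gene TCA17 (2.55) and the seripauperin gene PAU7 (2.54), with standard errors of 0.06 to 0.18. Phosphate genes led the falls. The high-affinity phosphate transporter gene PHO84 fell from 714 ± 22 to 121 ± 27.3 CPM (log2 -2.56 ± 0.13, adjusted p = 2.11e-08, edgeR), with SPL2 (-3.64), PHM6 (-3.03), the acid phosphatase gene PHO12 (-2.58), the sodium-phosphate cotransporter gene PHO89 (-2.44) and the polyphosphate synthesis gene VTC3 (-1.87). The small nucleolar RNAs snR3 (-1.98 ± 0.51) and snR58 (-1.84 ± 0.41) varied widely between libraries.

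In total edgeR called 3592 of 9700 features higher and 3086 lower, with 6934 at an unadjusted p under 0.05. With a minimum fold of 1.5 the counts were 2792 and 584, and with 2 they were 1941 and 162. Coding features split 1457 higher to 2559 lower of 5694 (36.3% of calls higher), but 1888 to 1705 (52.5%) when scaled on coding features alone, which moved the coding median from -0.14 to -0.003. Falls of coding genes smaller than that shift depend on the scaling.

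Known NMD substrates rose as a list: 17 of 23 were higher and 1 lower (17 and 1 adjusted over the list alone), with a median log2 of 0.87 (adjusted p = 7.19e-08, camera, or adjusted p = 0.149 with an estimated correlation). The iron reductase gene FRE2 went from 18 to 76.9 CPM (log2 2.09), CPA1, whose upstream reading frame is a textbook NMD trigger, from 130 to 484 CPM (1.89; its feature overlaps YOR302W), and the telomerase gene EST2 from 11.2 to 55.3 CPM (2.30). The remaining members called higher were STN1, EST1 (1.39, overlapping BNA5), EST3 (1.49), TEN1 (1.64), COX19 (1.22), ADR1 (0.99), RPL22B (0.96), ALR1 (0.87), CTF13 (0.87), GBP2 (0.70, overlapping SGF29), PPR1 (0.52), CRS5 (0.49), SUS1 (0.24) and SPT10 (0.19, overlapping MCO6). The copper regulator gene MAC1 was lower (-0.18), and COX23, CTR2, CAD1, ASF1 and SRG1 did not pass (SRG1 adjusted p = 0.0827, or 0.0467 with the replicate block, edgeR). With coding scaling the list had 17 higher and 0 lower of 21 tested. Of 2 mRNAs regarded as resistant, GCN4 rose slightly (log2 0.22 ± 0.05, adjusted p = 0.00367, edgeR) and YAP1 did not pass (0.07, adjusted p = 0.28).

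Other lists with a rise included telomere maintenance, where 8 of 13 were higher and 3 lower (median 0.85, adjusted p = 0.00312, camera, or 0.266 with an estimated correlation), among them EST2 and STN1, while the telomere-binding RAP1 fell (-0.68). Arginine synthesis had 9 of 12 higher and 1 lower (median 0.39, adjusted p = 0.0275, camera, or 0.266 with an estimated correlation), led by CPA1, ARG8 (1.23, overlapping PPM2) and the mitochondrial carrier gene ORT1 (0.69). Meiosis and sporulation had 8 of 11 higher (median 1.10, adjusted p = 0.0152, camera, or 0.266 with an estimated correlation), with the kinase gene IME2 at 2.18, the synaptonemal genes ZIP1 at 1.81 and HOP1 at 1.10, and SPO13 at 1.61. The 3 alpha-specific genes tested were higher in these a cells (median 1.06, adjusted p = 0.0366, camera, or 0.266 with an estimated correlation): SAG1 by 2.02, MATALPHA2 by 1.06 (overlapping BUD5) and STE3 by 0.37. Counts adjusted over each list alone were the same for these lists.

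The translation apparatus moved the other way. Of 138 cytosolic ribosomal protein genes 130 were lower and 2 higher (131 and 2 adjusted over the list alone), with a median of -0.46 (adjusted p = 1.2e-12, camera, or 0.266 with an estimated correlation), and -0.33 when scaled on coding features alone. RPL22B (0.96) and RPL8A (0.21, adjusted p = 0.00524, edgeR) were the pair that rose. Ribosome biogenesis had 22 of 23 lower (23 adjusted over the list alone, median -0.53, adjusted p = 4.6e-06, camera, or 0.281 with an estimated correlation), including NOP56 (-0.67), NOP4 (-0.69), NOP7 (-0.61) and UTP15 (-0.60). Glycolysis and fermentation had 16 of 18 lower and 2 higher (median -0.37, adjusted p = 0.00608, camera, or 0.296 with an estimated correlation), with TPI1 at -0.61, ADH1 at -0.55, FBA1 at -0.49 and GPM1 at -0.44. Exosome and nuclear decay genes had 17 of 22 lower (median -0.25, adjusted p = 0.0048, camera, or 0.281 with an estimated correlation), including the helicase gene MTR4 (-0.51) and the poly(A) polymerase gene PAP2 (-0.57), but 8 lower and adjusted p = 0.0619 when scaled on coding features alone. NMD and decapping factors had 13 of 17 lower, the deleted NAM7 among them, and 3 higher (median -0.29, adjusted p = 0.0121, camera, or 0.281 with an estimated correlation). The call was lost without NAM7 (adjusted p = 0.361, camera) and when scaled on coding features alone (4 higher, 8 lower, adjusted p = 0.0619). Members included the decapping gene DCP1 at -0.73, DCP2 at -0.31, the helicase gene DHH1 at -0.42 and the exonuclease gene XRN1 at -0.44. NMD4, EBS1 and NMD2 (0.21) rose in that list.

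Smaller list shifts followed. Oxidative phosphorylation had 13 of 28 lower and 2 higher (median -0.16, adjusted p = 0.0275, camera, or 0.281 with an estimated correlation), led by the cytochrome c gene CYC1 (-0.65) and ATP5 (-0.43), but 8 lower, 7 higher and adjusted p = 0.32 when scaled on coding features alone. The a-specific genes had 6 of 7 lower (median -0.69, adjusted p = 0.0152, camera, or 0.266 with an estimated correlation), including the protease gene BAR1 (-0.77) and the exporter gene STE6 (-0.69). Haploid pheromone genes had 7 of 12 lower and 2 higher (median -0.33, adjusted p = 0.0275, camera, or 0.266 with an estimated correlation, 0.164 with coding scaling), with the arrest factor gene FAR1 at -1.02. Sulfur and methionine genes had 13 of 23 higher and 3 lower (13 and 4 adjusted over the list alone, median 0.27, adjusted p = 0.314, camera), or 13 and 1 with coding scaling (median 0.40, adjusted p = 0.0409, camera), with MET1 at 2.15 and MET10 at 0.96. Gcn4 targets had 2 higher and 9 lower of 20 (2 and 8 adjusted over the list alone, median -0.12, adjusted p = 0.11, camera), or 3 and 3 with coding scaling (median 0.01). Pyrimidine synthesis had 5 higher and 4 lower of 9 (adjusted p = 0.786, camera), with URA10 at 1.26 and URA1 at 0.76. Lysine synthesis had 2 higher and 4 lower of 8 (median -0.10, adjusted p = 0.446, camera), or 2 and 2 with coding scaling (median 0.03).

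The environmental stress list had 7 higher and 3 lower of 20 (6 and 3 adjusted over the list alone, 10 and 3 with the replicate block); its median (0.08) and mean (0.16) were positive while camera gave a fall (adjusted p = 0.957). With coding scaling it had 13 higher and 2 lower, a median of 0.21 and a rise by camera (adjusted p = 0.293). The chaperone genes SSA3 and HSP26 were at 1.75 and -0.70. Hsf1 chaperones had 6 of 13 lower (median -0.09, adjusted p = 0.174, camera), including HSC82 (-0.49). With coding scaling they had 2 higher and 2 lower (median 0.04). The iron regulon had 5 higher and 8 lower of 15 (6 and 8 adjusted over the list alone, median -0.22, adjusted p = 0.415, camera), or 6 and 6 with coding scaling (median -0.09). The reductase gene FRE3 was at 1.84, the oxidase gene FET3 at -0.88 and FIT2 at -1.09. Copper genes had 4 higher and 4 lower of 12; their median was -0.05 (0.04 with coding scaling), their mean 0.12 (adjusted p = 0.957, camera), and the copper transporter gene CTR1 was at -0.57. Stationary phase genes had 3 higher and 1 lower of 9; their median (0.10) and mean (0.31) were positive while camera gave a fall (adjusted p = 0.957) or, with coding scaling, a rise (adjusted p = 0.792), with SNZ1 at 1.34. Of 2 auxotrophy loci tested HIS3 was higher (0.54). Of 6 neighbours of the deleted genes STE11 was higher (0.19) and ISF1 (-0.33) and SEC14 (-0.21) lower (adjusted p = 0.489, camera). With coding scaling these neighbours had 2 higher and 0 lower.

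SUTs and XUTs rose broadly in the upf1 deletion, and CUTs did not. SUTs had 545 of 744 higher and 28 lower (median log2 1.08), and XUTs 1082 of 1491 higher and 45 lower (median 1.07), with odds ratios of 5.31 and 6.01 for a higher call against the other features (p = 4.99e-97 and 2.42e-203, Fisher's exact test; features are not independent replicates). Features free of same-strand overlap with a gene gave medians of 1.07 for 645 SUTs and 1.08 for 1393 XUTs. The share of all counts on SUTs went from 0.263% to 0.872% and on XUTs from 0.356% to 1.1%. CUTs had 152 higher and 69 lower of 501 (median 0.07), and the second CUT annotation 155 and 208 of 690 (median -0.14). Odds ratios for a higher call were 0.729 and 0.47 (p = 0.00144 and 2.07e-17, Fisher's exact test), against other features that include the SUTs and XUTs. Set against coding features alone, CUTs had more higher calls (30.3% against 25.6%) and fewer lower calls (13.8% against 44.9%). At least 2-fold, 104 of 501 CUTs rose against 441 of 5694 coding features. The second annotation had 22.5% higher and 30.1% lower.

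**Figure D2:**
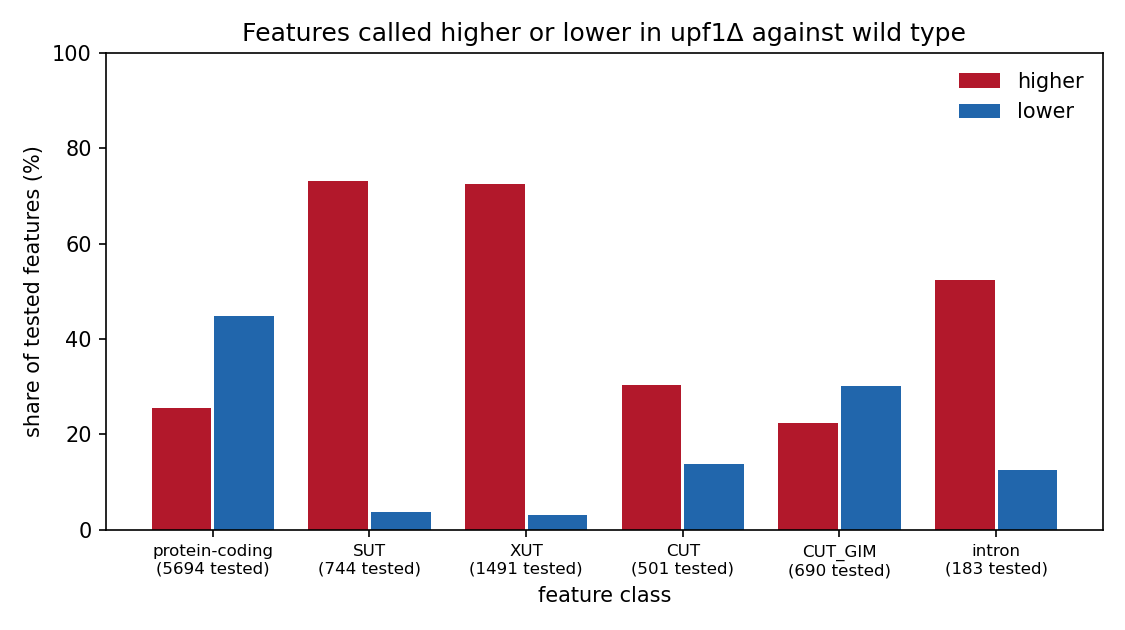
Share (%) of tested features called higher or lower in the upf1 deletion by feature class; bars are shares of the class. SUTs (545 of 744) and XUTs (1082 of 1491) were mostly higher, and coding features had more lower (2559) than higher calls (1457), a split that turned to 1888 higher and 1705 lower with scaling on coding features alone.

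Introns of ribosomal protein genes rose while their exons fell. Of 86 such introns 70 were higher and 1 lower, with a median log2 of 0.87 against -0.46 for the exons (p = 9.8e-11, camera, or 0.0447 with an estimated correlation). The RPL28 intron rose 11.6-fold (log2 3.54 ± 0.09, adjusted p = 2.73e-10, edgeR), the RPL22B intron 6.91-fold, the RPL30 intron by a log2 of 2.52 and the RPS13 intron by 2.32. Intron density was 1.14% to 1.27% of exon density in wild type and 3.05% to 3.18% in the upf1 deletion (log2 difference 1.40, exact permutation p = 0.1, the smallest possible with 3 against 3). Introns of other genes had 23 higher and 7 lower of 75 (median 0.09; density difference 0.15, exact permutation p = 0.3). In the second series the density difference for ribosomal protein genes was 0.34 in the nmd4 deletion, 0.42 in the ebs1 deletion and 0.40 in the labelled double deletion (exact permutation p = 0.2 each, with the pairing left out). Over same-numbered pairs each mutant was higher in 3 of 3, by 0.28 to 0.44, 0.33 to 0.48 and 0.20 to 0.57 (exact sign-flip p = 0.25, the smallest that 3 pairs can give). All 3 mutants were set against the same wild-type libraries, so these rises are not independent of each other. A shared rise cannot be told apart from low values in those libraries. Between mutants, the median intron minus exon change of the labelled double deletion was 0.041 against nmd4 and -0.022 against ebs1.

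**Figure D3:**
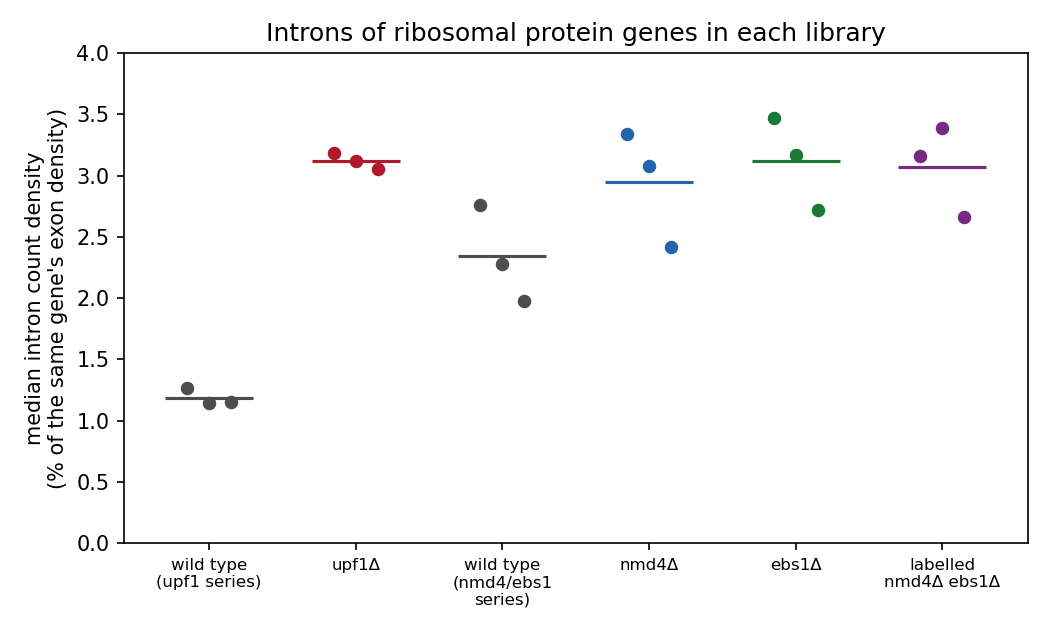
Intron density of ribosomal protein genes as a percentage of exon density (y axis) in each of 18 libraries by group; points are libraries and lines are group means. Values were 1.14% to 1.27% in the upf1 series wild type and 3.05% to 3.18% in the upf1 deletion.

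The nmd4 comparison asked which transcripts respond to loss of NMD4 alone. BIL1 (YOR304C-A, a formin regulator of polarity) rose by a log2 of 0.75 ± 0.10 (adjusted p = 0.031, edgeR), HRT1, the RING subunit of SCF ubiquitin ligases, by 0.72 ± 0.11 (0.0461), the secretory factor gene KSH1 by 0.69 ± 0.10 (0.0409) and LTO1, an iron-sulfur adaptor gene, by 0.61 ± 0.08 (0.033). All 4 were also higher in the upf1 deletion. NMD4 was the 1 lower feature. edgeR called these 5 of 10148 features, with 516 at an unadjusted p under 0.05. DESeq2 called 12 higher and 2 lower, and the replicate block gave 9 higher, adding the telomerase gene EST3 (0.70, adjusted p = 0.0281, edgeR). The higher calls numbered 2 without wild-type replicate 1, 1 without replicate 2, and 0 without wild-type replicate 3 or any of the nmd4 deletion's 3 replicates.

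Parentheses in the lists that follow give the median, the adjusted p of camera and the adjusted p with an estimated correlation. Ribosomal proteins (median -0.17, adjusted p = 2.69e-15, camera, or 0.725 with an estimated correlation), sulfur genes (-0.17, 0.000514, 0.725), pyrimidine synthesis (-0.18, 0.00265, 0.62, 1 higher and 3 lower adjusted over the list alone), glycolysis (-0.12, 0.0102, 0.725) and ribosome biogenesis (-0.10, 0.0366, 0.725; 0.0956 with coding scaling) were lower in the nmd4 deletion. The iron regulon was higher (0.18, 0.000514, 0.725). The NMD and decapping list (adjusted p = 6.34e-05, camera, or 0.62 with an estimated correlation) lost its call without NMD4 (adjusted p = 0.416, camera). With coding scaling copper genes passed (adjusted p = 0.0264, camera). With the replicate block arginine synthesis, copper genes and Hsf1 chaperones also passed (adjusted p = 0.0416, 0.0416 and 0.0465, camera). Known NMD substrates had a median of 0.07 (adjusted p = 0.442, camera), with 1 of 23 higher adjusted over the list alone.

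Loss of EBS1 raised more transcripts. BIL1 rose by a log2 of 0.94 ± 0.10 (adjusted p = 0.00305, edgeR), EST3 by 0.92 ± 0.16 (0.0408), the mitochondrial enzyme gene PPT2 by 0.89 ± 0.12 (0.0131), TCA17 by 0.87 ± 0.10 (0.00578) and the chromatin remodeller gene HTL1 by 0.81 ± 0.12 (0.0207). The drug exporter genes QDR3 (0.79) and FLR1 (0.58), HRT1 (0.73), the SUMO-targeted ligase gene SLX8 (0.65), ASA1 (0.64), the DNA glycosylase gene NTG2 (0.61) and ISC10 (0.60) followed. edgeR called 36 features higher, 25 of them coding, 4 SUTs, 5 XUTs and 2 of the second CUT annotation, and 1 lower, EBS1 itself (1287 at an unadjusted p under 0.05). The replicate block gave 327 higher (186 coding, 53 SUTs, 59 XUTs) and 244 lower (222 coding), DESeq2 162 and 66, and a fit of only the 6 libraries compared 0. Without wild-type replicate 2 there were 7 higher calls, without wild-type replicate 3 there were 11, and without ebs1 replicate 1, 2 or 3 there were 3 each. Without wild-type replicate 1 there were 15 lower calls.

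Known NMD substrates rose in the ebs1 deletion with a median of 0.20 (adjusted p = 9.41e-05, camera, or 0.264 with an estimated correlation); EST3 and STN1 (0.54 ± 0.10, adjusted p = 0.0481, edgeR) passed, and 7 of 23 did adjusted over the list alone. The telomere list had the same 2 genes (4 adjusted over the list alone, adjusted p = 0.0594, camera, or 0.00138 with coding scaling, where the iron regulon also passed at 0.0426). Lists that were lower, with the same values in parentheses, were ribosomal proteins (median -0.27, adjusted p = 6.84e-24, camera, or 0.407 with an estimated correlation; 45 called lower with the replicate block), oxidative phosphorylation (-0.26, 1.22e-07, 0.407), ribosome biogenesis (-0.20, 0.000129, 0.768, 5 lower with the block), pyrimidine synthesis (-0.23, 0.0181, 0.407, 1 higher and 3 lower adjusted over the list alone), glycolysis (-0.15, 0.024, 0.768), exosome genes (-0.09, 0.024, 0.797) and Gcn4 targets (-0.10, 0.032, 0.768). The last 4 lost their call with coding scaling (adjusted p = 0.082, 0.107, 0.123 and 0.165 in that order, camera). The NMD and decapping list (-0.07, 3.99e-05, 0.407) lost its call without EBS1 (adjusted p = 0.981, camera). Alpha-specific genes had a median of 0.20 and a mean of -0.50 (adjusted p = 0.737, camera).

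**Figure D4:**
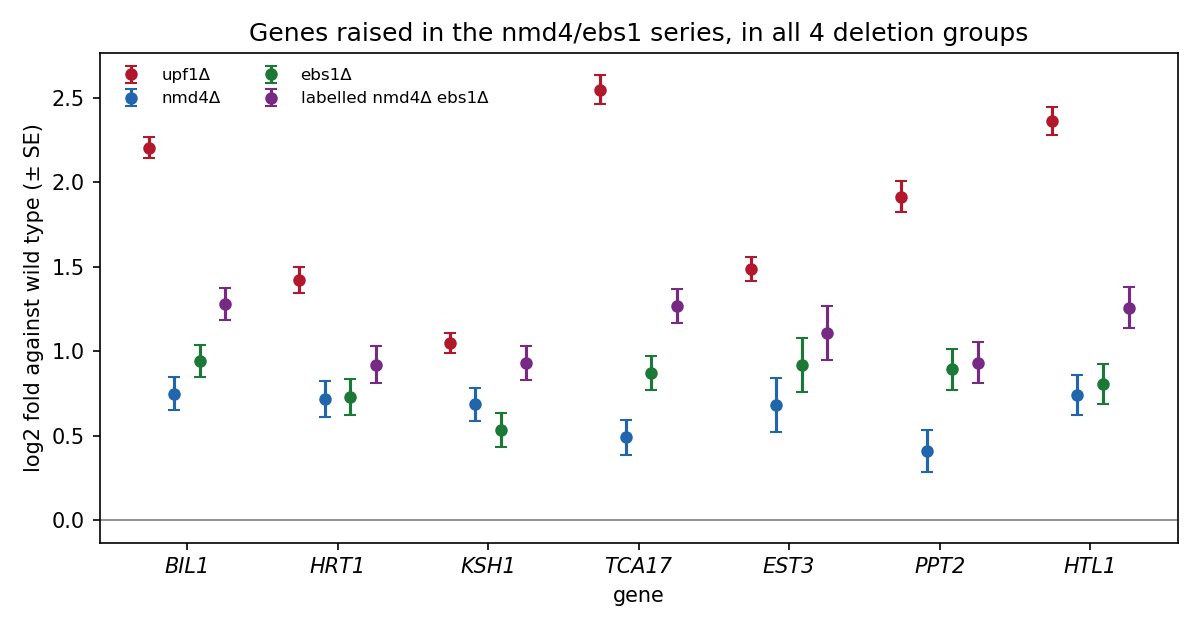
log2 change against wild type (y axis) of BIL1, HRT1, KSH1, TCA17, EST3, PPT2 and HTL1 in the upf1, nmd4 and ebs1 deletions and the libraries labelled nmd4 ebs1 double deletion; points are fitted values and bars are standard errors. BIL1 was at 0.75, 0.94 and 1.28 in the last 3.

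In the libraries labelled nmd4 ebs1 double deletion, where NMD4 was not lost and the background differed, the coding genes that led the ebs1 deletion stood highest after AFB1, an alpha-cell barrier gene, once the deleted, mating-type and auxotrophy genes of the lists were left out (AFB1 log2 3.60 ± 0.18, adjusted p = 2.03e-07, edgeR). BIL1 rose by 1.28 ± 0.10 (1.06e-05), TCA17 by 1.27 ± 0.10, HTL1 by 1.26 ± 0.12, EST3 by 1.11 ± 0.16 (0.0035), PPT2 and KSH1 by 0.93, HRT1 by 0.92, PET18 by 0.90, the telomere capping gene TEN1 by 0.83 ± 0.17 (0.0275), NBL1 by 0.83 (overlapping AIM46) and KTI11 by 0.82. The lysine synthesis genes LYS9 (log2 -0.70 ± 0.10, adjusted p = 0.00287, edgeR) and LYS20 (-0.60) fell. TOH1 (-0.76), GYP8 (-0.69), the glycerol gene GPD2 (-0.57) and the mitochondrial kinase gene POS5 (-0.51) also fell, and HMRA1 went from 26.6 ± 7.09 CPM to 0 counts. edgeR called 204 higher (98 coding, 41 SUTs, 45 XUTs) and 39 lower (26 coding), with 1510 at an unadjusted p under 0.05. Leaving out the deleted, mating-type and auxotrophy genes of the lists gave 198 and 30. The replicate block gave 525 (269 coding, 91 SUTs, 113 XUTs) and 368 (324 coding), DESeq2 288 and 122, and a fit of only these 6 libraries 34 and 21. The higher calls numbered 120 and 121 without wild-type replicates 2 and 3, and 88, 101 and 104 without replicates 1, 2 and 3 of the labelled double deletion; the lower calls numbered 25 without its replicate 2 or 3.

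Known NMD substrates had 4 of 23 higher there (EST3, STN1, TEN1 and FRE2 at 0.38; 7 higher and 1 lower adjusted over the list alone, median 0.16, adjusted p = 0.000987, camera, or 0.13 with an estimated correlation). Telomere genes had 3 higher (4 adjusted over the list alone, adjusted p = 0.0361, camera, or 0.546 with an estimated correlation, 0.0563 with the replicate block). Lysine synthesis had 3 of 8 lower, LYS4 (-0.47) included (1 higher and 6 lower adjusted over the list alone, 5 lower with the block, adjusted p = 5.45e-05, camera, or 0.13 with an estimated correlation). Ribosomal proteins (median -0.24, adjusted p = 8.11e-11, camera, or 0.546 with an estimated correlation; 34 lower with the block) and, with the same values in order, oxidative phosphorylation (-0.18, 0.000851, 0.546), ribosome biogenesis (-0.19, 0.00624, 0.692), glycolysis (-0.20, 0.0116, 0.653), exosome genes (-0.13, 0.034, 0.692) and sulfur genes (-0.19, 0.0403, 0.692, 0.0563 with the block) were lower. The last 3 lost their call with coding scaling (adjusted p = 0.0794, 0.201 and 0.201 in that order, camera). The NMD and decapping list had 1 higher, NMD4, and 1 lower, EBS1 (adjusted p = 0.00334, camera, or 0.546 with an estimated correlation and 0.388 without these 2 genes). The iron regulon passed with the block (adjusted p = 0.0339, camera) and with coding scaling (0.0184).

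Set against the nmd4 deletion, the labelled double deletion had TCA17 higher by 0.78 ± 0.10 (adjusted p = 0.00189, edgeR), NTG2 by 0.61, ISC10 by 0.60, BIL1 by 0.53 ± 0.10 (0.026), STN1 by 0.51 (0.0475) and the autophagy gene ATG12 by 0.48. AFB1 was higher by 3.83, and GYP8 (-0.77), LYS9 (-0.71) and POS5 (-0.53) were lower. NMD4 itself was higher by 4.68 (adjusted p = 6.13e-08, edgeR). edgeR called 29 higher and 27 lower (16 coding each, 661 at an unadjusted p under 0.05), or 23 and 18 without the deleted, mating-type and auxotrophy genes of the lists. The block gave 110 higher, DESeq2 84, and coding scaling 24 higher and 16 lower (60% higher against 50%). Higher calls were 19 and 17 without nmd4 replicates 1 and 3, and 17, 18 and 16 without the labelled double deletion's replicates 1, 2 and 3. NMD substrates had 1 higher, STN1 (5 adjusted over the list alone, 3 with the block, adjusted p = 0.00138, camera, or 0.111 with an estimated correlation). Lysine synthesis had 1 lower (6 adjusted over the list alone, adjusted p = 3.06e-05, camera, or 0.111 with an estimated correlation) and telomere genes 1 higher (4 adjusted over the list alone, adjusted p = 0.0408, camera, or 0.654 with an estimated correlation). Oxidative phosphorylation (median -0.15, adjusted p = 0.00713, camera, or 0.974 with an estimated correlation) and ribosomal proteins (median -0.07, adjusted p = 0.0408, camera, or 0.983 with an estimated correlation) were lower.

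Set against the ebs1 deletion, the labelled double deletion differed at the auxotrophy loci MET17 and LYS2 and at mating-type genes. AFB1 was higher by 3.92, RDT1 (a gene in the mating-type recombination enhancer) went from 5.78 ± 1.23 CPM to 0 counts, as did HMRA1, and GYP8 (-0.95), LYS9 (-0.66) and POS5 (-0.45) were lower. NMD4 was 1.54 times the ebs1 deletion's level (log2 0.63, adjusted p = 0.651, edgeR). edgeR called 15 higher and 27 lower (8 and 15 coding, 183 at an unadjusted p under 0.05). Without the deleted, mating-type and auxotrophy genes of the lists there were 10 and 19 (3 and 7 coding), with AFB1, HMRA1 and RDT1 still among them. Lysine synthesis had 1 lower (5 adjusted over the list alone, adjusted p = 9.01e-07, camera, or 0.0712 with an estimated correlation), and NMD substrates gave an adjusted p of 0.863 (camera). The interaction tested whether the labelled double deletion departs from the sum of the single deletions. It called 10 higher and 23 lower (6 and 12 coding, 283 at an unadjusted p under 0.05). AFB1 (4.15 ± 0.25, adjusted p = 2.53e-06, edgeR), NMD4 (3.86 ± 0.26, 5.83e-06), GYP8 (-1.02 ± 0.19, 0.0485), HMRA1 and RDT1 were among them. Without the same list members 5 higher and 15 lower calls were left, 1 and 4 of them coding. These coding calls were AFB1, GYP8, HMRA1, RDT1 and YNL146C-A, all tied to mating type or lying beside STE2 or MFA2.

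The features raised at least 2-fold in the upf1 deletion (1937, of which 1854 were tested in the second series) shifted upward in each other mutant. Their median log2 was 0.09 in the nmd4 deletion (63.9% positive; p = 1.07e-05, camera, or 0.00526 with an estimated correlation), 0.28 in the ebs1 deletion (84%, p = 2.89e-30 or 7.4e-06) and 0.32 in the labelled double deletion (84.6%, p = 3.01e-23 or 2.32e-05), against 1.56 in the upf1 deletion. Over same-numbered pairs the means were 0.10 ± 0.04, 0.28 ± 0.05 and 0.32 ± 0.03 (SD, n = 3). The labelled double deletion exceeded the nmd4 deletion by 0.24 (p = 4.64e-18, camera, or 8.38e-05 with an estimated correlation) and the ebs1 deletion by 0.05 (p = 0.049, camera, or 0.132 with an estimated correlation, 0.0754 with the block), and the interaction was -0.04 (p = 0.191). By class, coding genes, XUTs and SUTs had medians of 0.30, 0.26 and 0.29 in the ebs1 deletion, 0.31, 0.32 and 0.33 in the labelled double deletion, and 0.08, 0.07 and 0.07 in the nmd4 deletion (p = 0.131 for XUTs and 0.0638 for SUTs with an estimated correlation). CUTs, here of both annotations together, and introns had medians of 0.21 and 0.21 in the nmd4 deletion (p = 0.0201 and 0.123 with an estimated correlation), 0.27 and 0.24 in the ebs1 deletion (p = 0.0115 and 0.14), and 0.37 and 0.26 in the labelled double deletion (p = 0.0106 and 0.238). The 151 upf1-lowered features tested gave medians of 0.01, -0.13 and 0.04 (p = 0.25, 0.24 and 0.566, limma's camera, or 0.785, 0.781 and 0.892 with an estimated correlation), and camera passed for nmd4 with the replicate block (p = 0.0447).

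**Figure D5:**
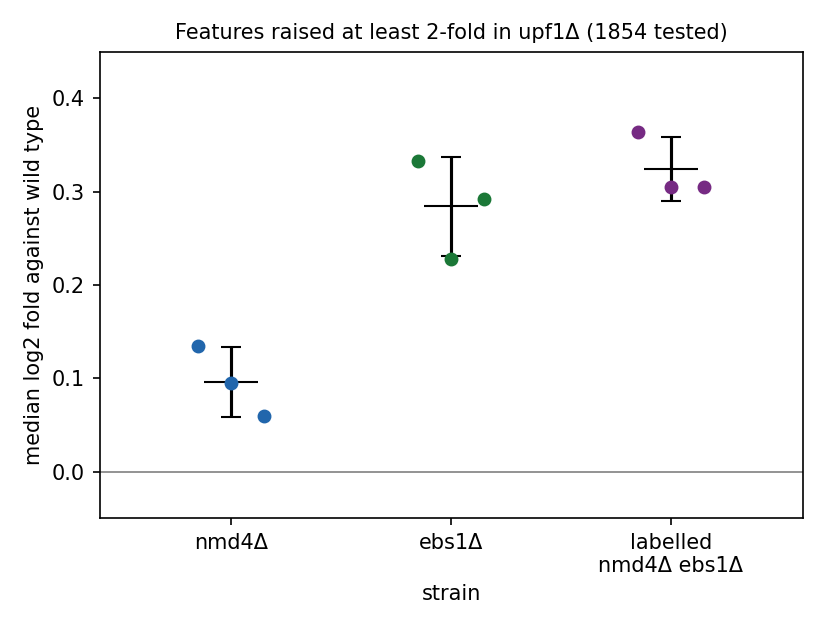
Median log2 change against wild type (y axis) of the 1854 features raised in the upf1 deletion, by mutant; points are same-numbered pairs, lines are means and bars are SD. The ebs1 deletion pairs lie at 0.33, 0.23 and 0.29 and the nmd4 deletion pairs at 0.14, 0.10 and 0.06.

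Calls overlapped likewise. BIL1, HRT1, KSH1 and LTO1 made 4 of 4 nmd4 calls higher in the upf1 deletion (1.5 if independent; p = 0.0181, Fisher's exact test), against 35 of 36 for ebs1 (13.2 if independent; p = 1.21e-14) and 181 of 193 for the labelled double deletion (70.8, 1.65e-64), while 11 of 28 of its lower calls were lower in the upf1 deletion (9, 0.424). With the replicate block 294 of its 352 lower calls were (113.6 if independent; p = 2.42e-91, Fisher's exact test), as were 223 of 240 lower calls for ebs1 (77.4, 8.92e-90). Across features, which are not independent replicates, log2 changes correlated with those of the upf1 deletion at r = 0.18, 0.47 and 0.39, or by rank at 0.24, 0.52 and 0.53. Mutants of the second series share their wild type, which alone gave a simulated r of 0.53, or 0.54 with replicate effects simulated. Over 10129 features the observed r was 0.71 for nmd4 and ebs1, 0.51 for nmd4 and the labelled double deletion and 0.61 for ebs1 and the labelled double deletion. Covariances were 0.067, 0.066 and 0.0909 against simulated values of 0.0471, 0.0472 and 0.0473, leaving differences of 0.0199, 0.0188 and 0.0437, or 0.0355, 0.0349 and 0.0598 with replicate effects simulated. These pairs shared 4, 4 and 36 higher calls, against 0.0142, 0.0782 and 0.704 if independent and 0 in the simulation. The simulation held no changed feature, so its value was fixed in advance. The independent values leave out the shared wild type. Neither reference can show sharing beyond that of a common control.

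The upf1 effect was then tested against each other effect. It came from another series than the other effects, so a series or culture condition that changes a response cannot be told apart from the deletion. The biological coefficient of variation was 0.08 in the upf1 series, 0.18 in the second and 0.153 in the joint fit. DAL7 differed by 3.05 from the nmd4 effect, 2.70 from the ebs1 effect and 2.77 from the labelled double effect (adjusted p = 1.75e-10, 7.14e-10 and 2.99e-10, edgeR). DAL5 (2.65, 2.21 and 2.31), the non-coding RNA RME2 (2.30, 2.07 and 2.10), FLR1 (2.48, 2.06 and 2.07) and the carnitine transferase gene YAT2 (2.08, 2.06 and 2.02) also differed from each. FRE2 was among the 6 genes with the smallest p against the nmd4 and ebs1 effects (1.99 and 1.74), and THI22 against the labelled double effect (2.51, adjusted p = 2.21e-09). edgeR called 2157 features higher and 563 lower in the upf1 effect than in the nmd4 effect (79.3% higher), 1751 and 308 against ebs1 (85%), and 1692 and 264 against the labelled double deletion (86.5%). RLE scaling gave 1845 and 1812 (50.5%), 1509 and 1150 (56.8%), and 1486 and 972 (60.5%); it moved the median of all features from 0.01, 0.01 and 0.01 to -0.15, -0.13 and -0.12. SUTs were 400 higher to 3 lower of 770 against nmd4, 346 to 1 against ebs1 and 333 to 5 against the labelled double deletion. XUTs were 692 to 2 of 1580, 586 to 1 and 554 to 4.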

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

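The tests of leftover NMD4 sequence and of reads beside the NMD4 coding region, the look at the neighbour of NMD4, and the labelings kept within replicate numbers were chosen only after the result was seen. Genes of mating type, lysine synthesis and NMD4 stood out because the interaction test, which asks whether the libraries labelled nmd4 ebs1 double deletion depart from the sum of the single deletions, passed its threshold. Among genes expected from an alpha background, the fitted interaction was 13.75 for MF(ALPHA)1, 12.93 for MF(ALPHA)2, 6.36 for STE3, 4.15 for AFB1 and 3.84 for SAG1. Among a-cell genes it was -4.08 for STE6, -5.30 for BAR1, -5.32 for ASG7, -5.61 for MFA1, -6.06 for STE2, -6.76 for AGA2 and -8.99 for MFA2. LYS2, deleted in the alpha parent, gave -12.06. HMRA1 gave -11.97 and RDT1 -10.57, and fitted values of genes at or near 0 counts depend on the prior count. YNL146C-A (-4.03) lies next to MFA2 and GYP8 (-1.02) next to STE2. NMD4 gave 3.86. Of 100 free labelings of the 12 libraries, the real one included, which leave out the replicate pairing, 2 gave 10 or more higher calls (highest other 32) and 3 gave 23 or more lower calls (highest other 53). Of 100 labelings kept within replicate numbers, 5 gave as many higher calls (highest other 21) and 2 as many lower calls (highest other 117). The free labelings break the replicate pairing, so their shares cannot exclude chance. Within replicate numbers the share was under 0.05 for lower calls but not for higher calls, so chance was not excluded for the higher calls. The labelings with several times the real count point to a structure of the samples, whose cause was not tested. For single genes the gap was wider than any spread between libraries: MF(ALPHA)1 stood at 845 to 1070 CPM in the 3 labelled double libraries and at 0.0882 to 0.653 CPM in the other 9.

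NMD4 was not lost in the libraries labelled nmd4 ebs1 double deletion. Leftover sequence of the allele in the nmd4 deletion libraries was excluded, since the lowest labelled double library held 17.8 times the CPM of the highest nmd4 deletion library. Libraries that lack EBS1 alone cannot be told apart from a true double deletion by the upf1-raised features: the change from the ebs1 deletion to the labelled double deletion correlated with the nmd4 effect at r = 0.056 across features, which are not independent replicates, against an upper bound of 0.055 in simulations of equal groups, or 0.045 (SD 0.035) with replicate effects simulated. An allele built differently, with reads of at least 64.1 CPM beside the coding region (657 of the feature's 1273 bases), may also explain the counts, since the table holds no position within a feature. YLR363W-A, beside NMD4 and overlapping GRX8, was at 50.1 ± 6.42 CPM against 37.3 ± 6.81 CPM in the ebs1 deletion (adjusted p = 1, edgeR, or 0.0215 with the replicate block). Background was not separable from genotype in that comparison. The same gene was at 47.6 ± 11.8 CPM in the nmd4 deletion and 40.2 ± 6.84 CPM in wild type. The nmd4 deletion was higher in each same-numbered pair, but the libraries of these groups overlapped.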

How the results depend on the processing

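The fits without the labelled double deletion and of the set free of overlap, the alternatives for feature classes and introns, and the list tests on coding features alone or without deleted genes were chosen only after the data were seen. Each group had 3 libraries, with 14243384 to 31452109 counts each. Of 6360 checks of 477 named-gene results 5907 kept direction and call, 173 passed where the reported test had not, 280 no longer passed and 0 reversed. Of 95 list tests, most had no call to lose. With an estimated correlation 40 lost their call, and only the a-specific and alpha-specific lists of the labelled double deletion kept one. With fry 21 lost theirs. Under RLE scaling 94 stayed on their side of the threshold, and on coding features alone 12 lost and 5 gained a call. The medians of the upf1-raised set kept direction and call in every setting run, at 0.071 to 0.13, 0.252 to 0.326 and 0.3 to 0.371 for nmd4, ebs1 and the labelled double deletion without 1 library. The cause of the changes that follow was not tested, except that fewer libraries or features entered where the setting says so.

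With the replicate block, higher calls were 9 for nmd4, and higher and lower calls 327 and 244 for ebs1 and 525 and 368 for the labelled double deletion, with 110 higher against nmd4; shared higher calls were 9 for nmd4 with ebs1, 9 for nmd4 with the labelled double deletion, and 277 for ebs1 with it, with 171 shared lower calls. Among named genes, lists and feature classes the block gained 51 calls, all in the direction of the reported value, lost 3, moved 24 class counts and left 550 results on their side. DESeq2 gave 12 and 2 for nmd4, 162 and 66 for ebs1, 122 lower for the labelled double deletion and 84 higher against nmd4. DESeq2 with the block gave 31 and 26 for nmd4, 404 and 590 for ebs1, 543 and 666 for the labelled double deletion, 149 and 45 against nmd4, 23 higher against ebs1 and 21 higher in the interaction. RLE scaling gave 23 higher for ebs1, and shared higher calls of 1 for nmd4 with ebs1 and 23 for ebs1 with the labelled double deletion. The last count to move was that of the upf1 effect minus nmd4 deletion effect: genes lower numbered 1812 with RLE scaling, 1443 with no filter, 1689 with the block and 1901 with DESeq2. For the upf1 effect minus ebs1 deletion effect: genes lower numbered 1150, 752, 1279 and 1321 in these settings. For the upf1 effect minus double deletion effect: genes lower numbered 972, 719, 1216 and 1144.

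Coding features alone gave 1888 and 1705 for upf1, 7 higher for nmd4, 71 and 2 for ebs1, 19 lower for the labelled double deletion, 16 lower against nmd4, 8 and 14 against ebs1, and 6 and 12 in the interaction. A minimum fold of 1.5 left 584 lower for upf1. Only the libraries compared gave 0 higher for nmd4 (516 at an unadjusted p under 0.05 in all 12 libraries, edgeR; 12 by DESeq2), 0 for ebs1 (1287; 162 by DESeq2), 34 and 21 for the labelled double deletion and 18 higher against nmd4. Without the labelled double deletion libraries edgeR called 0 higher for nmd4 and 3 for ebs1. Without mating, auxotrophy, sulfur, lysine and pheromone genes, lower calls were 17 against nmd4 and 17 against ebs1, and the interaction had 6 and 14.

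Without 1 library, counts ran from 0 to 2 higher and 1 to 2 lower for nmd4 (0 without any nmd4 replicate or wild-type replicate 3), 3 to 38 and 1 to 15 for ebs1 (3 without any ebs1 replicate), 88 to 176 and 25 to 57 for the labelled double deletion (88 without its replicate 1), and 16 to 21 higher against nmd4 (16 without the labelled double deletion's replicate 3). The upf1-lowered set ran from -0.214 to 0.4 for nmd4 (0.4 without wild-type replicate 3), -0.301 to 0.253 for ebs1 (reversed at 0.253 without wild-type replicate 3) and -0.264 to 0.374 for the labelled double deletion (reversed at -0.191 without wild-type replicate 1 and at -0.264 without its own replicate 3). With no fold minimum that set gave -0.049, -0.117 and -0.129, reversing for nmd4 and the labelled double deletion, and the block gave 0.055 for nmd4, where camera then passed. fry reversed the direction of camera for 3 lists of the upf1 deletion: environmental stress (median 0.08), copper (-0.048) and stationary phase (0.101).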

Other observations

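The 3 lists written after the data were seen, the tests of a culture condition for phosphate genes and of features outside the raised set, and the set free of overlap were chosen only after the result was seen. In the upf1 deletion 14 of 16 PHO regulon genes were lower and 1, the glycerophosphoinositol permease gene GIT1 (log2 2.43), higher, with a median of -1.43 (p = 1.65e-14, camera; 0.0498 with an estimated correlation). Of 8 allantoin and urea genes 6 were higher (median 1.23; p = 1.43e-08, camera; 0.00717 with an estimated correlation). Of 149 subtelomeric genes 104 were higher and 16 lower (105 and 18 adjusted over the list alone; median 1.02; p = 1.32e-12, camera; 0.00629 with an estimated correlation), many of them members of families that share sequence. In the ebs1 deletion allantoin genes had a median of 0.31 (p = 5.5e-05, camera; 0.00867 with an estimated correlation; 4 higher adjusted over the list alone), with DAL2 at 0.66 (adjusted p = 0.0558, or 0.0123 with the replicate block, edgeR), and subtelomeric genes 0.17 (p = 3.24e-06; 0.00141). In the libraries labelled nmd4 ebs1 double deletion, where NMD4 was not lost, DAL2 (0.59) and DAL7 (0.47) were higher, as were 8 of 152 subtelomeric genes. The allantoin and subtelomeric lists were written after the values were seen. Their p-values in the upf1 and ebs1 deletions therefore cannot show a rise beyond chance. Among introns of genes outside the ribosome, the median change was 0.30 in the nmd4 deletion (p = 4.21e-10, camera; 0.00153 with an estimated correlation), with a density difference of 0.35 (exact permutation p = 0.1, the smallest possible).

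The PHO regulon fell in the upf1 deletion by a mean log2 of 1.36 over same-numbered pairs (SD 0.20, n = 3). The list was written after its falls were seen, so these tests cannot show that the fall is beyond chance or exclude an explanation. In the 12 libraries of the other series the list's mean ranged over 0.89 once group means were taken off. That range does not bound the variation between cultures of the upf1 series. The 10000 random sets matched on length, GC content and expression level had medians of -0.449 to 0.364, against -1.43 for the list. Members picked for their falls made that gap (permutation p = 1e-04, the smallest possible) likely in advance. A medium or culture condition shared by the upf1 deletion cultures cannot be told apart from the genotype: the smallest drop in a pair was 1.13, and a shared condition may give that too.

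Features raised in the upf1 deletion were higher in the ebs1 deletion. A replicate batch was excluded, since the lowest of the 3 same-numbered pairs had a set median of 0.228. The 10000 random sets matched on length, GC content and expression level had medians of -0.016 to 0.041, against 0.278 for the raised set. That argues against these properties as matched, in 5 bins each, while differences within a bin were not tested. Features are not independent, so the random sets give no p-value for chance: other splits of the libraries gave absolute medians up to 0.152. Reads shared with overlapping features were excluded, since 775 members free of overlap had a median of 0.278. A candidate explanation is that loss of EBS1 weakly moves what loss of UPF1 moves: across 7650 features outside the raised set, which are not independent replicates, the log2 changes correlated at r = 0.332 against an upper bound of 0.033 in simulations of unchanged groups, or 0.034 with replicate effects simulated. It remains a hypothesis, found and tested on the same data.

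For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05; 1 of 10, the real one, gave as many calls in each, against a highest other of 0, also among the splits that part as many same-numbered pairs: 3592 higher and 3086 lower for upf1, 4 and 1 for nmd4, 36 and 1 for ebs1, 204 and 39 for the labelled double deletion, 29 and 27 against nmd4, and 15 and 27 against ebs1. The upf1-raised set had real medians of 0.086, 0.278 and 0.32 for nmd4, ebs1 and the labelled double deletion, against highest others of 0.059, 0.152 and 0.148 (1 of 10 each). The upf1-lowered set did not stand out, at 0.008, -0.126 and 0.036 against 0.566, 0.542 and 0.698 (10, 8 and 8 of 10). For the upf1 effect minus each other effect, labels were permuted within each series. Against nmd4, 4 of 100 labelings gave at least 2157 higher calls (highest other 2673) and 6 at least 563 lower (2472). Against ebs1, 5 gave at least 1751 higher (2648) and 7 at least 308 lower (2614). Against the labelled double deletion, 5 gave at least 1692 (2529) and 7 at least 264 (2458). All labelings as large kept the upf1 libraries together, as 7 of 100 did, and so carried the upf1 effect. These shares only count how many such labelings were drawn and decide nothing about chance. With the upf1 libraries parted the highest counts were 6 and 19, 6 and 19, and 6 and 17.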
